A study of Homo sapiens with 7 samples.

How the data were processed

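Enhanced reduced representation bisulfite sequencing (ERRBS), in which genomic DNA is digested at MspI sites and bisulfite treatment turns unmethylated cytosine into a base read as thymine, was used to read methylation at single CpG positions. The cells were haematopoietic stem and progenitor cells of the mouse, sorted as lineage-negative, Sca1-positive and Kit-positive (LSK). The organism and source fields of the labels name human and AML blast cells, whereas the sorting protocol, the genome builds and the coordinates in the files are those of mouse, and the data were treated as mouse.

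Per the authors' readme, adapters were removed with far, reads were aligned and methylation was called with Bismark, CpGs covered 10 to 400 times were kept, and positions aligned to mm9 were moved to mm10 with liftOver. Bismark 0.5.4, Bowtie 0.12.7 and CASAVA 1.7 are named in the submitters' processing notes. All coordinates are mm10 positions as deposited. In each library's file the authors deposited, for each CpG and strand, the read coverage and the percent of reads with C and with T. The files were deposited per library, with no pooling, scaling or normalisation stated. Methylated reads were recovered as coverage times percent, and 100% of entries in each library gave a whole number within 0.01. Coverage of 10 to 400 in the files was checked and held in the 7 libraries. The upper limit removes the most deeply covered positions, repeats among them, and levels there are not analysed here.

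The authors also deposited tables of differentially methylated CpGs for Idh2 and for Dnmt3a mutants. Per the authors' readme, the Idh2 table was called with methylSig against 9 control libraries, with at least 3 samples supporting a difference, a q-value of at most 0.01 and a methylation change of at least 25%. The Dnmt3a table used the same controls and, per the authors' readme, a similar procedure. The score that the authors deposited for each CpG in these tables is the mutant minus control difference of 2 methylation estimates in percent, which are deposited beside it. The tables also give a gene symbol, a RefSeq identifier and a gene part code (I, P, EX, D, DW or G). The readme does not define these codes, so they are printed as they stand.

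The 4 Idh2 R140Q libraries were matched to their samples by title. The 3 wild-type libraries, A2, A3 and A4, carry the group name WT LSK but no sample name, and were used as replicates of that group without numbers. Per the authors' readme they come from another series and serve as controls here, so genotype and series of origin cannot be told apart. Site files of the 3 samples labelled WT LSK in the series, which the readme lists both as controls and as mutants of both genes, were not used here. Per-library data of Dnmt3a mutants were not analysed here. The labels name no separate animals, so p-values measure the spread between these samples, which may be technical.

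The tests, their thresholds, 13 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. CpGs on autosomes covered at least 10 times in each of the 7 libraries were analysed, with the strands of a CpG kept apart. Group means of methylation per library were compared with a two-sided exact permutation test over the 35 splits of 7 libraries into 4 and 3, whose smallest possible p is 0.0286. Differential methylation was tested on methylated and unmethylated reads with a logistic model of group, whose likelihood ratio was divided by an overdispersion per site. The overdispersion was moderated across sites with the squeezeVar method of limma and never set below 1, and the two-sided p from an F distribution was adjusted by the Benjamini-Hochberg method. CpGs were called at adjusted p under 0.05 and a difference of at least 25 percentage points. Tiles were fixed windows of 1 kb with at least 3 CpGs and were called at adjusted p under 0.05 and at least 10 points. CpG density was the number of covered CpGs within 250 bp on each side, in 3 classes divided at 9 and 39. Overlaps were tested with Fisher's exact test, two-sided unless stated.

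Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used. The moderation written in Python was checked against limma on 20000 of the observed CpGs and differed by a relative 1.0e-06 at most. The model was tested on simulated data made from the observed levels and coverages, with 200 features changed at each size. For the CpG comparison, 21 of the 1414688 simulated CpGs were called in error, 5.01% of unchanged CpGs had p below 0.05, and 24.5%, 37.0% and 49.5% of CpGs changed by 30, 40 and 50 points were recovered. For the tile comparison, 11 of 106526 tiles were called in error, 5.14% of unchanged tiles had p below 0.05, and 37.5%, 62.0% and 82.5% of tiles changed by 15, 25 and 40 points were recovered. With 200 features changed at each size, the calls in error were a larger share of the calls than of the features tested. As a share of the calls they lay above the adjusted threshold of 0.05 for CpGs and below it for tiles. Fewer features were changed than were called in the real data, so the adjusted threshold was stricter in the simulation. The shares recovered are therefore not the power of the real comparison.

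Promoters could not be tested, because a mouse annotation was not used here. The gene list test, which had been set for promoters, was therefore run at the CpGs that the authors' Dnmt3a table assigns to a list's genes, a choice made after the files had been seen. A list needed at least 10 covered CpGs, which 9 of the 13 lists had. These CpGs were picked by the authors on other mutant libraries but on control libraries that include the 3 used here. Named tiles were the 10 largest gains and 10 largest losses among called tiles in which the 4 mutant values lay on one side of the 3 wild-type values, and 1 of the losses is not reported here. Named genes were those at the 10 largest gains and losses of each deposited table and up to 4 members per list and table by largest change. The 5 genes with the most CpGs in each table were added after their values had been seen.

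Alternatives were a coverage minimum of 20, adding the X chromosome, CpGs covered in at least 3 mutant and 2 wild-type libraries, leaving out each library in turn, read-weighted means, Fisher's exact test on pooled reads, limma on logit methylation with an offset of 1 read, other thresholds, an upper limit on coverage, tiles of 500 bp or at least 5 CpGs, a wider density window, and the stronger changes of each deposited table. Alternatives added after seeing the data were summing the strands, keeping CpGs or tiles of 1 to 99% pooled methylation, an overlap background of tiles at 25 to 75% in the wild type, and read weights shared by the libraries. Reads carry no molecular identifiers, so intervals and limits for a count of 0 cover counting error only.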

Results

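Methylation of CpGs was measured by ERRBS in LSK cells, the sorted compartment that holds the haematopoietic stem cells of mouse bone marrow, from Idh2 R140Q mutants (n = 4 libraries) and wild-type controls (WT LSK, n = 3 libraries). Idh2 encodes a mitochondrial isocitrate dehydrogenase, and its R140Q form makes 2-hydroxyglutarate, an inhibitor of the TET enzymes that oxidise methylcytosine. The comparisons asked where methylation differed in Idh2 mutant cells, and how it stood at CpGs that the authors reported as changed in mutants of Dnmt3a, a de novo DNA methyltransferase. The 4 mutant libraries held 1602672, 1518354, 1580074 and 1547335 CpG positions, at median coverages of 87, 100, 96 and 109 reads and summed coverages of 154567486, 170533012, 168336768 and 190280045 reads. The wild-type libraries A2, A3 and A4 held 1887587, 1921363 and 2119582 positions, at median coverages of 129, 125 and 55 reads and summed coverages of 244037862, 246978296 and 119058586 reads. Reads summed over CpGs, here and in tiles, count a read once at each CpG it covers, so they exceed the number of separate reads. Across 1414688 autosomal CpGs covered at least 10 times in each of the 7 libraries, Pearson's r was 0.994 to 0.997 between wild-type libraries, 0.963 to 0.974 between mutant libraries and 0.960 to 0.979 between a mutant and a wild-type library. These correlations are across CpGs, which are not independent replicates. Per the authors' readme the wild-type libraries come from another series, so a difference between genotypes cannot be told apart from one between series.

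Idh2 itself had a single CpG in the authors' deposited table of Idh2 differences, at chr7 80095848 (RefSeq NM_173011, gene part codes DW and EX), where the mutant level was listed at 51.0% and the control level at 89.1%. In the libraries here that CpG stood at 51.2% ± 11.4 (SD, n = 4) in the mutants and 91.7% ± 1.1 (SD, n = 3) in the wild type, with 42 to 288 reads per library. The adjusted p of the limma-moderated logistic model was 0.054, so it was not called. Methylation calls do not show the mutation itself, and genotype was taken from the labels.

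Methylation was higher in the mutants when averaged over all autosomal CpGs. The mean was 36.26% ± 0.89 (SD, n = 4) in Idh2 R140Q and 33.93% ± 0.25 (SD, n = 3) in WT LSK, a difference of 2.33 percentage points (two-sided exact permutation test, p = 0.0286, the smallest the design allows). CpGs in sparse surroundings, with low CpG density, stood at 81.21% ± 0.84 in the mutants and 78.32% ± 0.52 in the wild type, and those of intermediate density at 23.32% ± 1.26 and 20.32% ± 0.18. The differences of 2.89 and 2.99 points each had an adjusted p of 0.0429 over the 3 classes in the exact permutation test. In dense CpG surroundings, which include CpG islands, the levels were 2.23% ± 0.59 and 1.12% ± 0.03, and the difference of 1.11 points did not pass (exact permutation test, adjusted p = 0.0571), although the 4 mutants lay above the 3 wild-type libraries in each of the 3 classes. With each CpG weighted by its reads the mean methylation difference turned to -2.62 points (exact permutation test, p = 0.17), and with the same weights for each library it was 2.25 points. At a coverage minimum of 20 the intermediate class differed by 2.85 points and no longer passed (exact permutation test, p = 0.057).

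**Figure D1:**
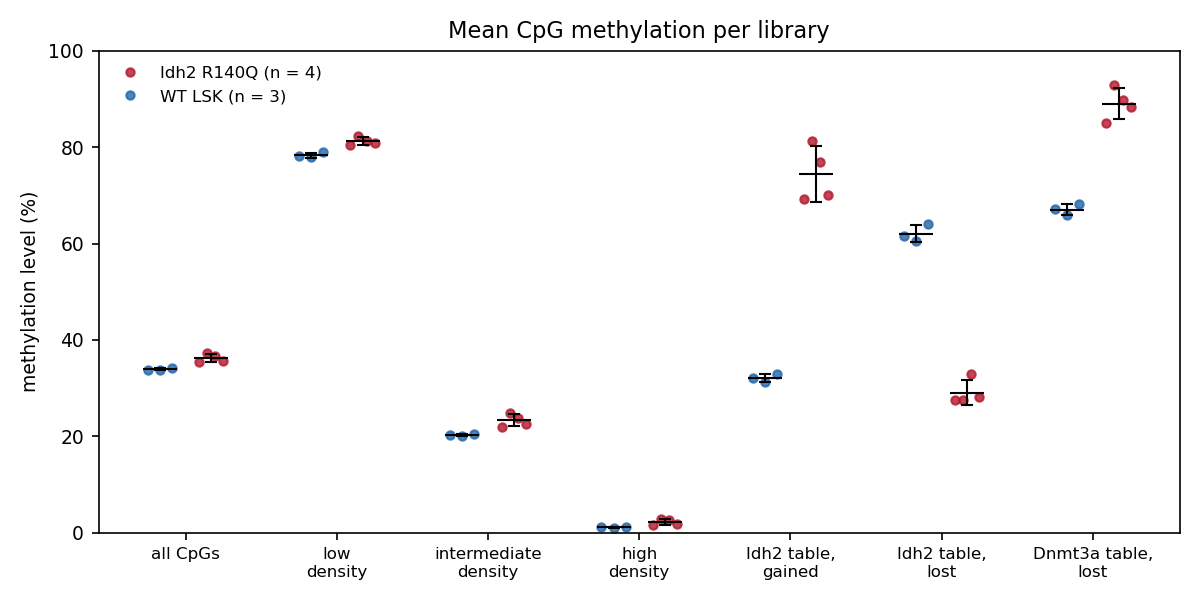
Mean CpG methylation level (%) in each library over 7 sets of CpGs, with points for libraries (red, Idh2 R140Q, n = 4; blue, WT LSK, n = 3), a bar at the group mean and whiskers of 1 SD. Over all CpGs the groups lie at 36.26% and 33.93%, and at CpGs that the authors' Dnmt3a table lists as lost the mutants lie at 89.03% and the wild type at 67.03%.

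Differentially methylated CpGs were nearly all higher in the mutants. Of the 1414688 CpGs tested, 8835 gained and 116 lost methylation, so that 98.7% of the 8951 called CpGs gained. Gained CpGs had a median wild-type level of 32.3%, a median mutant level of 84.3% and a median difference of 42.5 points, whereas lost CpGs fell by a median of 31.0 points. Low-density surroundings held 4748 gained and 95 lost CpGs, intermediate density 3401 and 20, and high density 686 and 1. At an unadjusted p below 0.05 in the limma-moderated logistic model, 162329 CpGs were higher and 17829 lower. The number of calls depended on single libraries: it was 342 without WT LSK A3, 927 without A2 and 3295 without A4, and 16785 and 14003 without mutant libraries 1 and 4. The lost CpGs numbered 5, 16 and 35 without A3, A2 and A4, and 350, 267, 292 and 259 without mutant libraries 1 to 4 in turn. Of 59 lost CpGs whose cytosine on the opposite strand was covered, 17 (28.8%) fell by at least 10 points there too, against 2893 of 3057 gained CpGs (94.6%) that rose by as much.

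The gain in percentage points was largest at CpGs that were partly methylated in the wild type. CpGs between 20 and 40% in the wild type stood at 49.9% ± 5.63 (SD, n = 4) in the mutants and 29.4% in the wild type, a difference of 20.48 points, and 2525 of these 24189 CpGs were called gained. The differences were 14.64 points at CpGs of 5 to 20%, 16.42 points at 40 to 60% and 9.87 points at 60 to 80%. At CpGs of 0 to 5% in the wild type the difference was 1.16 points, and at 95 to 100% it was -0.32 points. Because the wild-type libraries set both the class and the difference, the classes were set again in A2 alone and measured against A3 and A4. The 20 to 40% class then gained 18.26 points in low, 21.75 in intermediate and 22.41 in high CpG density, with an SD between mutant libraries of 4.07, 7.40 and 8.36 points. These classes were described without a test.

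**Figure D2:**
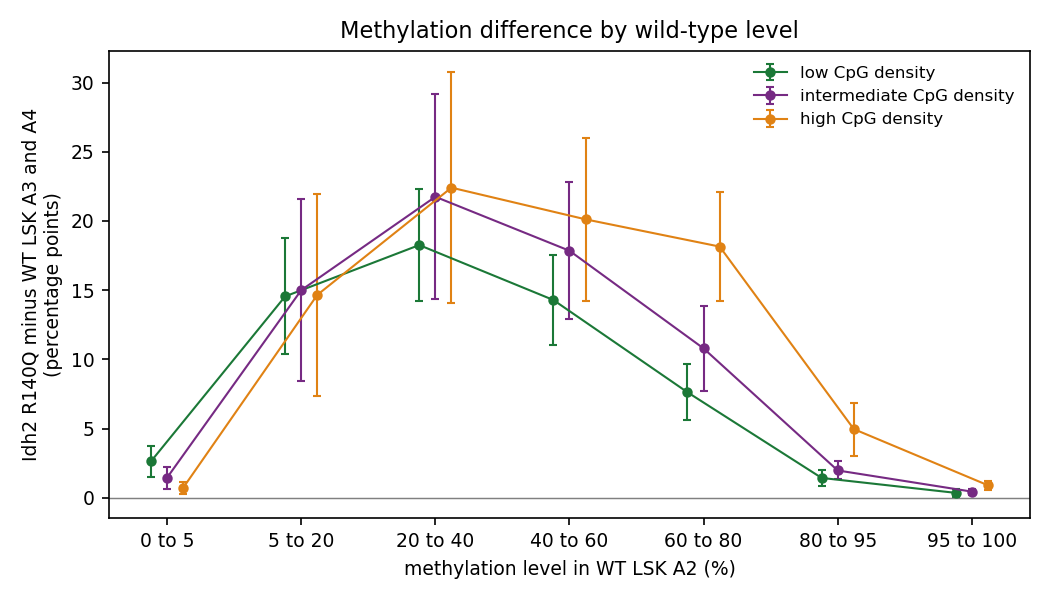
Difference in methylation (Idh2 R140Q minus WT LSK A3 and A4, percentage points) against the level in WT LSK A2 (%), for CpGs of low, intermediate and high CpG density, with points for the mean over the 4 mutant libraries and whiskers of 1 SD between them. The difference peaks at 20 to 40% in the 3 density classes, at 18.26, 21.75 and 22.41 points.

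Among fixed tiles of 1 kb, the largest gain lay at chr16 4640000 to 4640999, assigned by the authors' tables to Vasn, which encodes a membrane protein that binds TGF-beta (codes EX, I and P), and to Coro7, a coronin family gene (code I). Its level was 92.0% ± 3.2 (SD, n = 4) in the mutants and 8.3% ± 3.2 (SD, n = 3) in the wild type, from 187 to 1035 reads per library. The tile at chr17 36988000 to 36988999 at H2-M5, a class I histocompatibility gene (codes DW, EX, I and P), rose to 92.4% ± 3.1 against 16.4% ± 2.4, with 1861 to 4191 reads. Neighbouring tiles of Nr4a2, an orphan nuclear receptor, at chr2 57110000 to 57110999 (codes EX and I) and chr2 57109000 to 57109999 (code I), rose by 75.3 and 70.8 points, to 85.7% ± 5.6 and 98.7% ± 1.7. The tile at chr5 122734000 to 122734999 in Camkk2, a calcium-dependent kinase upstream of AMPK (code EX), stood at 83.6% ± 9.9 against 8.5% ± 1.6. At chr8 84784000 to 84784999 in Nfix, a nuclear factor I transcription factor (code I), the levels were 93.2% ± 2.8 and 19.8% ± 1.5, from 1155 to 5079 reads. The other gains of the 10 were at chr11 120186000 to 120186999 (2810410L24Rik, a transcript with a non-coding RefSeq identifier, codes DW and EX, 71.4 points), chr8 105268000 to 105268999 (Fbxl8, codes DW and EX, and Hsf4, a heat shock transcription factor, code P, 70.7 points), chr10 79946000 to 79946999 (Arid3a, an AT-rich DNA-binding factor, and Bc1, code I for both, 70.4 points) and chr9 121682000 to 121682999 (Sec22c, code EX, 70.2 points). Adjusted p-values of these 10 tiles in the limma-moderated logistic model ran from 7.8e-05 to 2.6e-03. None of the 10 lost its call under the alternatives that were run for it. The tile at chr2 57109000 to 57109999, with 3 CpGs and 47 to 429 reads per library, was not assessed at a coverage minimum of 20.

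Losses in tiles were smaller, and the calls of most named ones were lost when 1 library was left out. The largest, at chr11 99916000 to 99916999 by Gm11565 (code DW), stood at 47.3% ± 15.6 (SD, n = 4) in the mutants and 84.7% ± 3.8 (SD, n = 3) in the wild type, from 143 to 518 reads per library. Sdc1, which encodes the proteoglycan syndecan-1, had a tile at chr12 8773000 to 8773999 (code I) at 39.9% ± 5.9 against 69.8% ± 5.0, with 306 to 978 reads. At Nucb2, the gene of the nesfatin precursor, the tile at chr7 116681000 to 116681999 (code G) stood at 22.8% ± 15 against 56.5% ± 2.3. The tile by 4921531P14Rik at chr18 83352000 to 83352999 (code D) fell by 30.6 points. Of the 5 that the authors' tables assign to no gene, chr5 115236000 to 115236999 fell by 35.9 points, chr7 45813000 to 45813999 by 33.3, chr3 159385000 to 159385999 by 32.7, chr1 86229000 to 86229999 by 30.3 and chr7 79272000 to 79272999 by 29.7. Adjusted p-values of these 9 tiles ran from 8.3e-03 to 3.7e-02 in the limma-moderated logistic model, and the tile at Sdc1 kept its call under each alternative run for named tiles. The other 8 each lost it when at least 1 library was left out: without WT LSK A2, 8 tiles lost their call, without A3, 7, without A4, 2, without mutant library 3, 2, and without mutant libraries 1, 2 or 4, 1 each. Where a call was lost this way, the difference itself lay between -27.42 and -39.46 points, except at chr5 115236000 to 115236999, where it was -19.66 points without mutant library 3.

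**Figure D3:**
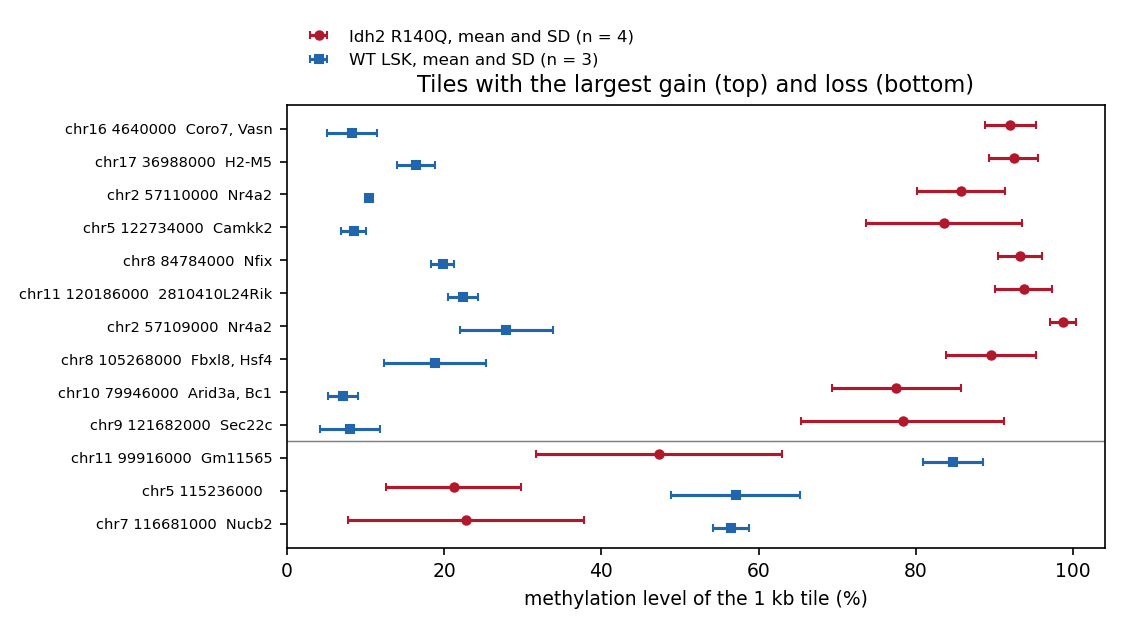
Methylation level (%) of the 10 tiles of 1 kb with the largest gain (top) and the 3 with the largest loss (bottom), labelled by chromosome, start and gene, with red circles for the Idh2 R140Q mean (n = 4), blue squares for the WT LSK mean (n = 3) and whiskers of 1 SD. Gains span 70.2 to 83.7 points, and in the losses the mutants read lower by between 33.7 and 37.4 points.

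Over all tiles, 4876 of 106526 gained and 142 lost methylation, so that 97.2% of the 5018 called tiles gained. The count of calls was 1653 without WT LSK A2, 1484 without A3 and 3003 without A4. Lost tiles numbered 28, 49 and 57 without A2, A3 and A4, and 231 without mutant library 1. With limma on logit methylation, 2583 tiles gained and 40 lost.

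The authors' deposited table of Idh2 differences lists 15783 CpGs, 15616 gained and 167 lost, at 4749 gene symbols. Mn1, a transcriptional coregulator gene altered in myeloid leukaemia, has 114 CpGs there, between chr5 111418442 and 111512376 (codes D, EX, G, I and P). At the 110 of them analysed here, methylation was 89.9% ± 3.5 (SD, n = 4) in the mutants and 30.2% ± 0.4 (SD, n = 3) in the wild type. Tspan4, a tetraspanin gene (chr7 141481955 to 141482597, code I), stood at 79.4% ± 11.8 against 10.9% ± 0.7 over 74 CpGs. Zfp316, a zinc finger gene (chr5 143253003 to 143255359, code EX), stood at 78.9% ± 17.2 against 19.8% ± 2.5 over 88 CpGs. Nfix stood at 86.6% ± 4.3 against 28.9% ± 1.3 over 71 CpGs, and Bc1 at 80.4% ± 5.1 against 33.4% ± 0.8 over 70 CpGs. The CpGs that the authors assign to Bc1 lie between chr10 79706894 and 80349301 (code I). A tile in that stretch is also assigned to Arid3a, so these CpGs may not belong to Bc1 alone. These 5 genes were taken after their values were seen, as those with the most CpGs in that table. The largest gains in the table lie at 2810410L24Rik, here at 84.4% ± 10.2 against 23.1% ± 0.8 over 49 CpGs, and Rabac1, a Rab acceptor gene (chr7 24951322 to 24955401, code D), here at 87.1% ± 7.1 against 22.1% ± 0.8 over 22 CpGs.

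Over the whole table, the 15156 gained CpGs covered here averaged 74.45% ± 5.76 (SD, n = 4) in the mutants and 32.06% ± 0.86 (SD, n = 3) in the wild type, and the 157 lost CpGs 29.08% ± 2.61 and 62.05% ± 1.78. Of the CpGs called gained here, 8014 of 8835 (90.7%) are in the table as gained, and 53 of the 116 lost CpGs are in it as lost. The table was made on the same 4 mutant libraries, so this is not independent evidence of direction. Of the 10 genes with the largest losses of the table, 7 had CpGs covered here, and 4 of these had a CpG called lost. Ptprd, a receptor tyrosine phosphatase gene (chr4 77588476, code G), had no methylated read among 138 in the 4 mutants, which allows a level of up to 2.17%, against 61.9% ± 10.9 (SD, n = 3) in the wild type. Chordc1 (chr9 18009900, code G) stood at 26.9% ± 3.9 (SD, n = 4) against 81.8% ± 1.9, and Npy5r, a neuropeptide Y receptor gene (chr8 66604042, code G), at 9.0% ± 5.8 against 48.1% ± 1.7. Adjusted p-values of these 3 CpGs were 0.0082, 0.0042 and 0.029 in the limma-moderated logistic model, and their cytosines on the opposite strand were not covered in each of the 7 libraries. A sequence difference at these positions, which can also be read as T, was not examined. Gm9926 (chr18 66596790 to 66678238, code G) stood at 34.8% ± 3.7 against 77.9% ± 5.8 over 2 CpGs, 1 of them called lost. The single CpG of Faim2 (chr15 99524875, code EX) was not called, at 10.8% ± 9.9 against 51.1% ± 11.1 from 11 to 155 reads (adjusted p = 0.085 in the limma-moderated model), and its cytosine on the opposite strand was 10.7 points higher in the mutants. Grik3 stood at 34.3% ± 11.1 against 21.8% ± 3.1 over 4 CpGs, with none called, and Ptchd2 at 52.8% ± 10.7 against 63.7% ± 3.1 over 2, with 1 called gained. The authors list 3 gained CpGs and 1 lost CpG for Grik3, and 1 of each for Ptchd2. These means mix both directions and do not show the lost CpG itself.

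Members of the 13 fixed gene lists that stand in the authors' deposited table of Idh2 differences carried gained CpGs almost throughout. So did that table as a whole, with 15616 of its 15783 CpGs gained, so direction says little about these lists. Whether list genes stood in it more often than other genes was not tested. Of 22 genes of stem cell identity and self-renewal, 12 were in the authors' deposited table, with 114 CpGs, none of them lost. Hlf, a transcription factor of haematopoietic stem cells (chr11 90347860 to 90385838, code I), stood at 88.4% ± 4.5 (SD, n = 4) in the mutants and 32.4% ± 3.3 (SD, n = 3) in the wild type over 31 CpGs. Prdm16, a stem cell maintenance factor (chr4 154499784 to 154634704, code I), stood at 86.3% ± 5.4 against 41.4% ± 0.7 over 26 CpGs, and Gata2, a zinc finger regulator of stem and progenitor cells (chr6 88152083 to 88202134, codes D, EX, I and P), at 77.9% ± 5.8 against 30.7% ± 7.1 over 12. Of 22 myeloid genes 7 were in the authors' deposited table, with 125 CpGs, all gained. Csf2ra, the alpha chain of the GM-CSF receptor (chr19 61225286 to 61226321, codes DW, EX and I), stood at 85.0% ± 7.3 against 22.5% ± 1.2 over 64 CpGs, and Gfi1, a transcriptional repressor of granulocyte development (chr5 107721503 to 107723548, codes EX, I and P), at 92.4% ± 2.7 against 41.9% ± 2.2 over 36. Of 35 HOX genes, which encode regulators of body axis patterning, 22 were in the authors' deposited table with 135 CpGs, all gained. Hoxa3 (chr6 52175477 to 52209646, code I) stood at 90.9% ± 4.5 against 54.3% ± 0.6 over 70 CpGs. Of 22 genes of Ras and JAK-STAT signalling 10 were in the authors' deposited table with 63 CpGs, all gained. Socs3, a feedback inhibitor of JAK-STAT signalling (chr11 117930581 to 117968341, codes D, DW, EX, I and P), stood at 68.4% ± 14.0 against 17% ± 2.7 over 22.

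Of 16 genes of the DNA methylation machinery 6 were in the authors' deposited table: Dnmt3a, Tet1, Tet2, Tet3 and Idh1 had gained CpGs only, and Idh2 its 1 lost CpG. Dnmt3a (chr12 3871756 to 3917997, codes D and I) stood at 84.7% ± 4.4 (SD, n = 4) against 39.5% ± 3.0 (SD, n = 3) over 10 CpGs. Tet1, which encodes a methylcytosine dioxygenase (chr10 62865697 to 62866303, code I), stood at 69.5% ± 2.2 against 29.6% ± 4.9 over 7 CpGs. Of 50 developmental transcription factors 35 were in the authors' deposited table, with 105 gained CpGs and 1 lost, at Foxa2. In the same authors' deposited table, the erythroid and megakaryocyte list had 6 of 18 members, the B lymphoid list 4 of 15 and the imprinted list 10 of 28, with gained CpGs only. The T and NK lymphoid list had 6 of 17 members, 5 with gained CpGs only and Bcl11b, a T cell transcription factor gene, with CpGs of both directions. The AML list had 14 of 30 members, 13 with gained CpGs only and Sfrp1, an antagonist of Wnt signalling, with a lost CpG, and the germline list 4 of 18, of which Sycp3, a gene of the meiotic chromosome axis, had a lost CpG. None of the 20 interferon and antigen presentation genes was in the authors' deposited table. Foxa2 and Sfrp1 were named after their values were seen.

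Gained CpGs called at these genes, adjusted over the list alone, with those adjusted over all CpGs in brackets, numbered 111 (78) of 113 for stem cell genes, 118 (88) of 118 for myeloid genes, 115 (60) of 132 for HOX genes and 58 (31) of 58 for Ras and JAK-STAT genes. Counted in the same way they were 24 (14) of 27 for methylation machinery genes, 30 (16) of 32 for erythroid and megakaryocyte genes, 59 (31) of 64 for AML genes, 96 (41) of 105 for developmental transcription factors and 25 (13) of 25 for imprinted genes. The small lists had 5 (3) of 5 for B lymphoid, 16 (9) of 18 for T and NK lymphoid and 5 (4) of 6 for germline genes. Lost CpGs called over the list alone numbered 1 each for the methylation machinery, T and NK lymphoid, AML, developmental and germline lists, and over all CpGs 1 each for the T and NK lymphoid, AML and developmental lists. Of the 15156 gained CpGs of the whole table covered here, 8014 were called gained over all CpGs. The counts of the lists were not tested against that share. As the table was made on these mutant libraries, these counts are not independent evidence of direction.

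CpGs that lost methylation in Dnmt3a mutants stood higher in Idh2 mutants. The authors' deposited table of Dnmt3a differences lists 9715 CpGs, 9714 of them lost, at 2702 gene symbols. At the 8778 lost CpGs covered here, methylation was 89.03% ± 3.29 (SD, n = 4) in Idh2 R140Q and 67.03% ± 1.17 (SD, n = 3) in WT LSK, a difference of 22.0 points (two-sided exact permutation test, p = 0.0286). The Idh2 mutant mean was above the wild-type mean at 8545 of them (97.3%), and 1672 were called gained and 0 lost. Mn1 stood at 95% ± 2.2 against 62.1% ± 1.2 over 98 CpGs of that table, and Gfi1 at 94.2% ± 2.2 against 50.3% ± 1.3 over 44. Tradd, the adaptor of TNF receptor 1 (chr8 105259003 to 105259355, codes DW, EX and I), which holds the largest loss of the Dnmt3a table, stood at 90.9% ± 7.8 against 47.9% ± 2.7 over 5 CpGs. The authors list 12 CpGs for Tradd there, at a mean control level of 72.5%, so the CpG with the largest loss may not be among the 5. Casz1, a zinc finger gene with 85 analysed CpGs there (chr4 148739243 to 148952995), stood at 88.0% ± 12.8 against 87.0% ± 0.6, and 1 library set this value: mutant library 1 read 69.0% and the others 93.0 to 96.7%, so that the difference was 1.0 points with it and 7.4 points without it. The 3 wild-type libraries are among the controls of the Dnmt3a table, and levels per library of Dnmt3a mutants were not analysed here.

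The lists fixed in advance were tested at those CpGs, with 9 of 13 lists holding enough of them. Myeloid genes differed most, at 93.73% ± 2.30 (SD, n = 4) in the mutants and 52.19% ± 1.32 (SD, n = 3) in the wild type over 48 CpGs, a difference of 41.54 points. Of these CpGs, 44 belong to Gfi1. Erythroid and megakaryocyte genes differed by 28.02 points (19 CpGs), methylation machinery genes by 27.85 (14 CpGs), Ras and JAK-STAT genes by 23.77 (18 CpGs), HOX genes by 21.55 (207 CpGs), stem cell genes by 18.02 (149 CpGs) and AML genes by 15.58 (44 CpGs). For these 7 lists the adjusted p was 0.0368 in the exact permutation test. Developmental transcription factors (22.66 points, 72 CpGs) and imprinted genes (10.98 points, 43 CpGs) did not pass (exact permutation test, adjusted p = 0.0571). In each of the 9 lists the 4 mutants lay above the 3 wild-type libraries. Calls adjusted over the list alone, with those adjusted over all CpGs in brackets, were 39 (32) gained for myeloid genes, 71 (34) for HOX genes, 45 (22) for stem cell genes, 27 (12) for developmental genes, 10 (4) for erythroid and megakaryocyte genes, 9 (6) for AML genes, 8 (6) for methylation machinery genes, 7 (5) for Ras and JAK-STAT genes and 4 (2) for imprinted genes. None was lost. The B lymphoid list had 1 (0) gained call among 4 CpGs, the T and NK lymphoid list 3 (0) among 9 and the interferon list 0 (0) among 2, and the germline list had no such CpG, so these 4 lists were not tested. The test asks whether a list's CpGs differed between genotypes, not whether they differed more than other CpGs of the table.

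The Idh2 and Dnmt3a tables overlapped in opposite directions. In the authors' deposited tables, 1939 gene symbols and 2505 CpGs stand in both, and each of the 2505 CpGs is gained in Idh2 and lost in Dnmt3a mutants. As 15616 of the 15783 Idh2 CpGs are gained and 9714 of the 9715 Dnmt3a CpGs are lost, nearly any shared CpG would be opposite. The direction of the shared CpGs thus adds little to their number. Among the 106526 tiles, 5524 held a CpG gained in the Idh2 table and 2997 a CpG lost in the Dnmt3a table, and 1500 held both, where independent lists would share 155.41 (odds ratio 24.78, one-sided Fisher's exact test, log10 of p -1146). Among tiles at 25 to 75% in the wild type, 955 were shared where independent lists would share 346.13 (odds ratio 8.31). Tiles with Idh2 losses shared 1 tile with Dnmt3a losses where 3.32 would be shared by independent lists (odds ratio 0.30, two-sided Fisher's exact test, p = 0.27). Among tiles at 25 to 75% in the wild type, that 1 shared tile stood against 7.35 for independent lists (odds ratio 0.12, two-sided Fisher's exact test, p = 0.0081). Neighbouring tiles are not independent, and both tables used the same 9 controls. Simulated unchanged groups against those controls shared 0 tiles in opposite directions in 10 draws, but at most 1 CpG was called in a draw, so this simulation could not have given an overlap.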

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

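The tests in this part were chosen after the results were seen, except the comparison of tile counts over other splits of the libraries. Of 168 sets of 4 mutant values examined with Dixon's test, 10 had 1 library apart from the other 3. Chance gives about 1 in 20 sets, or 8.4 of them.

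At CpGs of the Idh2 table listed as lost, mutant library 3 read 33.0% where the others read 27.6 to 28.1%. Six2, a developmental transcription factor gene, read 55.5% in mutant library 1 and 75.5 to 76.7% in the others, with the wild type at 27.1%. Dlk1, an imprinted gene, read 57.6% in mutant library 4 against 62.2 to 62.9%, and Ptchd2 68.6% in mutant library 4 against 45.0 to 48.9%. Hoxa5 read 97.9% in mutant library 2 against 93.0 to 93.6%, and the single CpG of Tdrd1 73.7% in mutant library 2 against 97.6 to 100%. At CpGs of the Dnmt3a table, mutant library 1 read 69.0% at Casz1 against 93.0 to 96.7%, and 82.2% at Cd5, a T cell surface gene, against 92.6 to 94.6%. There Etv6, a haematopoietic transcription factor gene, read 92.5% in mutant library 3 against 88.9 to 89.3%, and Nfix 95.2% in mutant library 2 against 92.1 to 92.5%. On the X chromosome, which the comparisons left out, 71 of 30164 CpGs were called gained and 4 lost, while the X means were 42.02% ± 1.25 (SD, n = 4) in the mutants and 43.96% ± 5.56 (SD, n = 3) in the wild type (two-sided exact permutation test, p = 0.6286).

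For the gain of methylation, chance assignment of the libraries was excluded at 0.05: 1 of the 35 splits into 4 and 3, the real one, gave as many called CpGs (8951, highest other split 667) and 1 of 35 as many called tiles (5018, highest other split 1553). Incomplete bisulfite conversion as the whole cause was argued against by a rise of 1.16 points at CpGs of 0 to 5% in the wild type beside 20.48 points at 20 to 40%, and by mitochondrial CpGs, where 1 of 7692 reads was methylated in the mutants (0.013%, 95% Wilson interval 0.002 to 0.074) and 31 of 36977 in the wild type (0.084%, 0.059 to 0.119). These mitochondrial reads are summed over CpGs and count a read at each CpG it covers, so the intervals may be too narrow. Wild-type libraries that read low against those of other series stay open: at CpGs of the Dnmt3a table the authors' deposited control estimate over 9 libraries differed by -0.02 points from the 3 used here, but those 3 are among the 9 and their weight is not known. That the 4 mutant libraries were made apart from the wild-type libraries stays open and cannot be told apart from genotype, since 0 wild-type libraries with a site file come from the series of the mutants. An effect of Idh2 R140Q on methylation and a change in the make-up of the LSK compartment both stay open and were not tested against each other.

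For the loss of methylation, signal limited to 1 strand of the CpG is a candidate explanation for part of the calls: the opposite cytosine fell by at least 10 points at 28.8% of the 59 lost CpGs where it was covered, beside a rise at 94.6% of 3057 gained CpGs. Median differences at the opposite cytosine were -0.4 points for lost and 40.6 points for gained CpGs. A segment of another strain linked to the Idh2 locus was argued against for the 125 of 142 lost tiles outside chromosome 7. On chromosome 7 it stays open, with 17 lost tiles where their share of tested tiles gives 9.51, and 2 within 10 Mb of the Idh2 CpG, too few to decide, where it gives 0.99. Lost CpGs without a covered opposite cytosine, end repair at MspI fragment ends, and sequence differences between the series elsewhere in the genome were not tested. An effect of genotype at the lost tiles stays open.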

How the results depend on the processing

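Alternatives chosen after seeing the data were the summed strands, the limits of 1 to 99% pooled methylation, the overlap background of 25 to 75% and the shared read weights; the others were planned. Of 255 values of the main results under alternatives, 206 kept their direction and their side of the threshold or stayed within 1.5 times the count (127 of 154 without 1 library, 79 of 101 under other settings). Without 1 library, mean differences had no test and so could not cross a threshold, and each counted as kept. The values that changed there were all counts of calls. The share of gains among called CpGs ran from 96.4 to 99.3% and among called tiles from 95.7 to 98.9%. Read-weighted methylation turned the mean methylation difference to -2.62 points (exact permutation test, p = 0.17), and weights shared by the libraries gave 2.25, so the turn comes from coverage that differs between libraries. At a coverage minimum of 20 the intermediate density class differed by 2.85 points (exact permutation test, p = 0.057), and the cause was not tested. Beside 8951 called CpGs (8835 gained, 116 lost), Fisher's exact test on pooled reads, which leaves out the spread between libraries, called 37948 (36567 and 1381), adjusted p under 0.01 left 1109 (1101 and 8), limits of 1 to 99% pooled methylation, which lower the number of tests, gave 16508 (16248 and 260), and a difference of at least 10 points gave 264 lost CpGs. Beside 5018 called tiles (4876 gained, 142 lost), limma on logit methylation called 2623 (2583 and 40), at least 5 CpGs per tile 3220 (3119 gained), a difference of at least 25 points 1923 (1902 and 21), and tiles of 500 bp 84 lost. The overlap of Idh2 and Dnmt3a losses passed with the background of 25 to 75% (odds ratio 0.12). Leaving out each library in turn gave 342 (without WT LSK A3) to 16785 CpGs (without mutant library 1), 337 to 16435 gained and 5 to 350 lost, and 1484 to 6459 tiles, 1435 to 6228 gained and 28 (without WT LSK A2) to 231 lost. The mean difference ran from 1.99 to 2.63 points and that at Dnmt3a table CpGs from 20.65 to 23.32; such values have no test, as 3 against 3 libraries cannot go below p = 0.1 in the two-sided exact permutation test and 4 against 2 not below 0.0667. Of 682 values of named genes 678 stayed the same; Gata4 and Tet1 moved, to 45.80 and 28.57 points at a coverage minimum of 20, and the gene Bcl11b, at -8.2 points over 2 CpGs, turned to 27.37 at that minimum and to 12.11 without mutant library 1 (-9.90 without WT LSK A3). Of 232 values of named tiles 207 kept their call and 25, all of losses, did not. With fewer libraries the moderated model has less power, but the cause of the fall without a wild-type library and of the rise without a mutant library was not tested. Promoters and the wider promoter window for lists were not run, since no mouse annotation was used here. No paired analysis was possible because the wild-type columns carry no replicate number and the mutant numbers are accession order. In data simulated at the observed coverages, with few CpGs changed, 49.5% of CpGs changed by 50 points were recovered. Depth was not varied there, so its part in the missed calls was not tested.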

Other observations

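The values of some further genes at CpGs of the Idh2 table, which was made on these mutant libraries, were as follows, and the genes were picked from the named genes after their values were seen. Six2, a kidney progenitor factor (chr17 85680181 to 85800840, codes D and G), stood at 70.9% ± 10.2 (SD, n = 4) against 27.1% ± 1.8 (SD, n = 3) over 17 CpGs, 8 of them called gained. Etv6, a haematopoietic ETS family repressor (chr6 134059669 to 134263099, codes EX and I), stood at 73.2% ± 10.1 against 28.8% ± 3.3 over 11 CpGs, 9 of them called. Zfpm1, the cofactor of GATA1 (chr8 122269220 to 122323114, codes D and I), stood at 71.2% ± 5.5 against 31.8% ± 2.4 over 21 CpGs, with 9 called, and Irf8, a factor of monocyte and dendritic cell development (chr8 120736910 to 120832401), at 61.4% ± 10.5 against 22.2% ± 1.2 over 9 CpGs, with 2 called. Tet3, a methylcytosine dioxygenase gene (chr6 83441389 to 83441906, codes I and P), stood at 54.7% ± 19.7 against 6.5% ± 0.7 over 4 CpGs, none of which was called. On the X chromosome, Bcor, a corepressor gene, stood at 69.4% ± 2.8 against 30.5% ± 1.4 over 23 CpGs, 12 of them called gained.

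At CpGs of the Dnmt3a table, Hlf stood at 95.6% ± 1.8 (SD, n = 4) in Idh2 mutants and 48.8% ± 5.3 (SD, n = 3) in the wild type over 9 CpGs, 8 of them called gained, and Nfix at 93.0% ± 1.5 against 59.8% ± 2.0 over 58, with 28 called. Hoxa5 stood at 93.5% ± 1.8 against 71.0% ± 0.5 over 80 CpGs, with 16 called, and Hoxa6 at 93.1% ± 1.8 against 71.6% ± 0.7 over 21, with 8 called. The CpGs assigned to Hoxa3, Hoxa5 and Hoxa6 lie in overlapping stretches of chr6 and are partly the same. H13, an imprinted gene (chr2 152696244 to 152707837, codes DW, EX and I), stood at 97.3% ± 0.3 against 91.9% ± 1.7 over 30 CpGs, with 1 called. The Dnmt3a gene itself stood at 91.6% ± 4.8 against 55.6% ± 4.0 over 6 CpGs, 4 of them called.

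The tests of the following pattern, the gain at CpGs of the Dnmt3a table, were written before their results were seen. CpGs matched on wild-type level and CpG density gained 10.2 points, and the Dnmt3a table CpGs gained 11.9 points more (SD between mutant libraries 0.5, range 11.1 to 12.2), which argues against the choice of CpGs by wild-type level and density as the whole cause. Simulated unchanged libraries read -0.37 points from the shared controls at CpGs picked as lost against them (10 draws). Picking CpGs this way favours controls that read high by chance, so the sign was set in advance and only the size is informative. Controls and unchanged libraries were drawn from the same level, so shared controls that differ by series were not covered and stay open. The separate series of the mutant and wild-type libraries, the make-up of the LSK cells and an effect of the Idh2 mutation at these CpGs stay open.

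A hypothesis, tested only after the pattern had been seen, was larger gains where the wild type is between the extremes, in every density class. With classes set in WT LSK A2 and differences measured against A3 and A4, the gain at 20 to 40% exceeded that at both extremes in 3 of 3 density classes: 18.26 points beside 2.63 at 0 to 5% and 0.35 at 95 to 100% in low density, 21.75 beside 1.45 and 0.44 in intermediate density, and 22.41 beside 0.72 and 0.90 in high density. The upper extreme is limited by the ceiling of 100% and says little. The lower extreme has room to rise, but an equal change in odds gives fewer points there than at 20 to 40%. The contrast with it thus depends on the scale of percentage points, and no other scale was tested. CpG density also went with the gain within some classes of wild-type level. At 60 to 80% the gain was 7.62 points in low and 18.15 in high density, and at 80 to 95% 1.43 and 4.96. At 5 to 20% the gain was alike, at 14.55 points in low and 14.66 in high density. Whether CpG density or the wild-type level is the weaker marker of where the gain lies was not tested.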
